A study of Homo sapiens with 6 samples.

How the data were processed

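Poly(A) RNA of 143B osteosarcoma cells, grown with 10% serum, was sequenced as paired-end libraries on an Illumina NovaSeq instrument, per the labels' protocols. The cells had received 80 nmol/L of a negative control siRNA or of a SIGLEC15 siRNA for 36 h, per the labels. The labels give 5 µg of input RNA, a RIN above 7 and an insert of 300 bp with a spread of 50 bp. Their extraction text also carries a passage on another species and another Illumina platform that does not match the organism and the instrument stated for these samples, and nothing from it was used. The siRNA sequences are not given in the sources used here.

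The deposited table holds 58825 genes with Ensembl IDs. The authors deposited counts per gene and library as whole numbers, and FPKM values beside them, per the file headers. The submitters' processing notes name HISAT, StringTie and edgeR, with no versions. How the counts were taken from the StringTie output, whether strand was used and which genome build was aligned to are not given in the sources used here. If the counts came from coverage or counted mates separately, counting intervals would be too narrow, so the intervals printed are for counting error on the values as given. Of the table's IDs 58552 are in GENCODE 29 (GRCh38), 58550 of these overlap it on the same strand, and 81.3% have the same start and end. Coordinates are printed as the table gives them. Symbols come from the table; 16806 of the 18910 tested IDs also have a symbol other than the ID itself in the gene name table used as a reference. No column was left without a sample (0 unmatched columns).

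Counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (minimum count 10, minimum total 15), TMM scaling, and the quasi-likelihood F test of SIGLEC15 siRNA against control siRNA over all 6 libraries with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and 29765 genes had no count in any library. For SIGLEC15 an exact two-sided permutation test on log2(CPM + 1) and an exact 95% Poisson interval of the ratio of summed counts were added. A gene at 0 in a whole group is given as a bound against 3 counts per library, which is 0.0485 to 0.051 CPM in the control libraries.

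The 34 gene lists were written before the data were examined and tested with camera (limma 3.58.1) on the edgeR count object at a preset correlation of 0.01, over lists with at least 5 tested members. A first look had given camera log2 CPM values, which called 8 lists, and the count object was settled on after that was seen. The log2 CPM version is kept as an alternative added after seeing the data. The genes named are SIGLEC15 and DUSP1; among genes that passed, had groups fully apart and had a gene symbol, the 10 with the largest and the 10 with the smallest log2 fold change and the 4 with the smallest p in each direction; and up to 4 members with the smallest p of each list discussed. The rule was written before the data were examined, but 2 readings of it were settled after values were seen: clone-named genes without a symbol in the gene name table were passed over, and list members were named only if called. Genes outside the rule are marked where they are named; partners that overlap a named gene were named for that overlap, after their values were seen. Some genes that the rule takes are not reported here.

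Alternatives were limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1, quantile normalization, no filter beyond 1 count in total, a mean FPKM of at least 5, median-of-ratios size factors, the DESeq2 1.42.0 Wald test, the replicate number as a block, each library left out in turn, an estimated correlation in camera, and fry. The limma-trend and quantile settings were run on FPKM. The filter, size-factor, block and left-out-library settings were run on counts only, because the table held counts.

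The edgeR test, the camera test and the scan described below were tried on simulated data. In counts simulated for this comparison over 18378 tested genes, edgeR called 4 of 67 genes changed 1.5-fold (5.97%), 31 of 67 changed 2-fold (46.3%) and 49 of 66 changed 4-fold (74.2%), with 4 false calls and 0 wrong signs; changed genes were drawn at all levels of expression, weakly expressed ones included. Each simulated gene took the variance between libraries that the edgeR trend gives for its level. The spread of that variance between genes in the real data was left out. The shares and false calls therefore hold for the simulated setting and need not hold for the real test. A bound first set for the 4-fold share was missed and loosened, and the shares stand as found. In a simulated list test 1 of 33 lists was shifted, it was called, and 0 others were. All its members were shifted alike, by more than the median of any tested list in the real data. Genes were simulated independently, so this trial could not show false list calls that come from correlation between genes.

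For the closing section, every sequence of 7 bases was scanned over the longest annotated 3' UTR (at least 50 bases) of 13607 tested protein-coding genes (GENCODE 29). The signed z of the edgeR test was regressed on presence of the sequence, with UTR length, UTR GC content and expression level as covariates, and the extreme t over 16267 sequences, each present in and absent from at least 50 genes, was set against 1000 shuffles of genes within 20 bins of UTR length. A sequence planted in simulated data at a shift of -0.5 in z was ranked 1. Seeds of 61 microRNA families were written from general knowledge after the scan was seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.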

Results

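In 143B cells, a human osteosarcoma line, transfection of a siRNA against SIGLEC15 was followed by a 2.96-fold lower level of DUSP1, the phosphatase that switches off MAP kinases, and by lower levels of the immediate early genes EGR1 and JUN (n = 3 libraries per group). LAMC1 and COL4A2, which encode laminin and collagen chains of basement membranes, rose, and so did the NF-kB response genes PTGS2 and TNFAIP3. The YAP targets CCN2, CCN1 and ANKRD1 and the mitotic regulator FOXM1 fell. Some called members of the immediate early, NF-kB and YAP lists went the other way, among them BTG2, IL1B and LATS2. SIGLEC15 itself, a sialic acid-binding receptor of the Siglec family, was read near the detection limit in every library, and its difference between the groups did not pass the test. Lower expression also went with the sequence AGGCTCA in 3' UTRs, so silencing of other mRNAs by the siRNA stays a hypothesis. The changes are thus not shown to follow from loss of SIGLEC15.

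The data are poly(A) RNA-seq libraries from 143B cells 36 h after transfection with 80 nmol/L siRNA, 3 with a negative control siRNA and 3 with the SIGLEC15 siRNA. Libraries held between 57966691 and 67655254 gene counts, with a mean of 60764950 ± 1689559 (SD, n = 3) in the control group and 64092263 ± 5328431 (SD, n = 3) in the SIGLEC15 siRNA group. The 10 most abundant genes took 7.74% ± 0.147 (SD, n = 3) of the counts in the control group and 7.78% ± 0.161 (SD, n = 3) in the SIGLEC15 siRNA group. Mitochondrial transcripts took 6.12% ± 0.108 and 6.45% ± 0.27 (SD, n = 3 each). The first principal component of log2 CPM held 26.2% of the variance and separated the groups, with the control libraries between -49.27 and -30.45 and the SIGLEC15 siRNA libraries between 21.61 and 52.37. The second held 20.3% and did not separate them. On it control replicate 3 (63.82) and SIGLEC15 siRNA replicate 1 (37.88) lay apart from the other libraries (-27.67 to -19.51). No pair of libraries agreed within counting noise: the chi-square per degree of freedom lay between 55.87 and 68.28 within groups and between 87.38 and 110.3 across them.

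The first question was whether the siRNA lowered its target. SIGLEC15 (ENSG00000197046, chromosome 18, 45825512 to 45842556, plus strand, in the coordinates of the deposited table) had 12, 10 and 22 counts in control replicates 1, 2 and 3, and 12, 8 and 6 counts in SIGLEC15 siRNA replicates 1, 2 and 3. That is 0.241 CPM ± 0.103 in the control group and 0.136 CPM ± 0.0461 in the SIGLEC15 siRNA group (SD, n = 3 each). The summed counts, 44 against 26, gave a ratio of 0.561, with an exact 95% Poisson interval of 0.331 to 0.931 that covers counting error only. Between replicates the spread was wider. The edgeR log2 fold change was -0.82 (SE 0.598, 95% interval -2.24 to 0.602, Benjamini-Hochberg adjusted p = 0.529), and the exact two-sided permutation test on log2(CPM + 1) gave p = 0.2, where 0.1 is the smallest p that 3 against 3 libraries can give. With this spread between libraries, a lower level of the SIGLEC15 transcript could therefore be neither shown nor excluded.

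DUSP1 (ENSG00000120129, chromosome 5, 172768096 to 172771195, minus strand) was named for measurement before the data were examined. It fell from 48.98 CPM ± 1.29 to 16.57 CPM ± 1.05 (SD, n = 3 each), a log2 fold change of -1.56 (SE 0.0865, edgeR adjusted p = 0.00116). It passed the threshold under all 14 alternative settings, with log2 fold changes between -1.61 and -1.44.

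**Figure D1:**
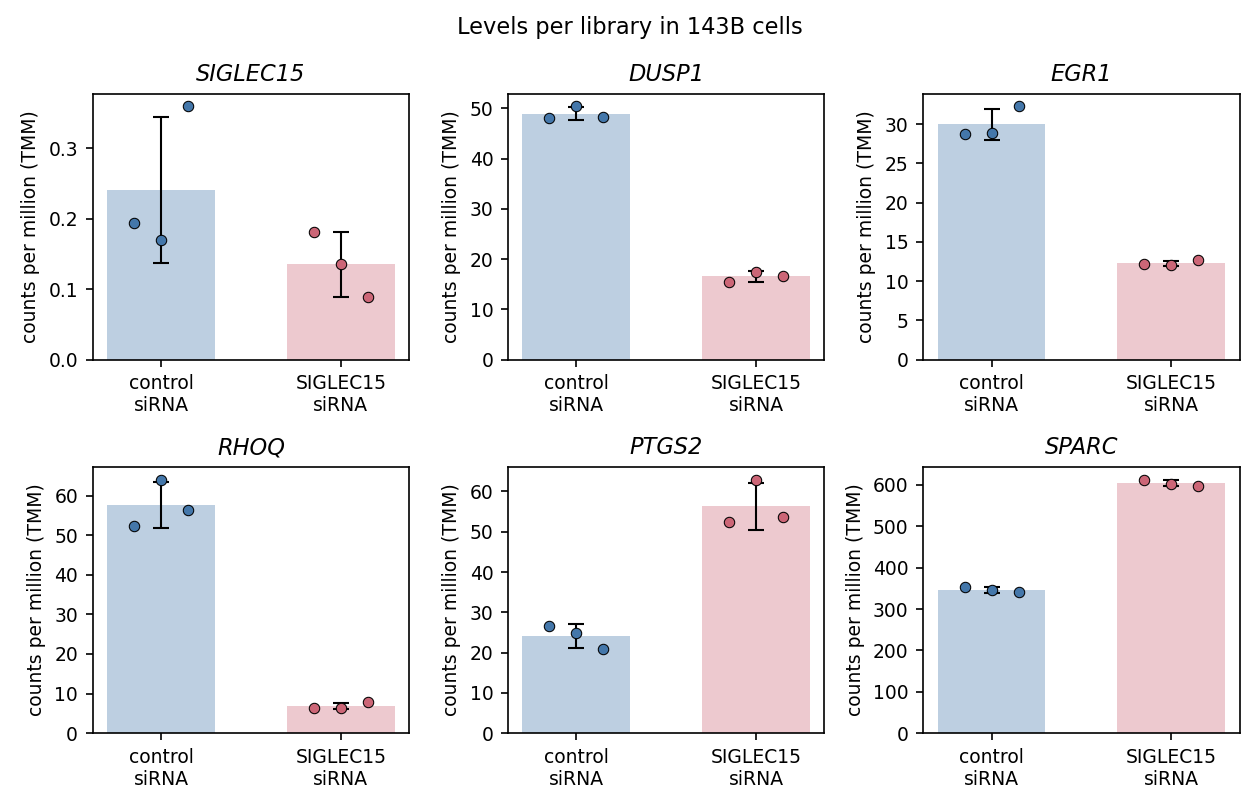
CPM, scaled by TMM, of SIGLEC15, DUSP1, EGR1, RHOQ, PTGS2 and SPARC in the control siRNA and SIGLEC15 siRNA libraries; points are libraries, bars are means and error bars are SD (n = 3 per group), and each panel has its own axis from 0. DUSP1, EGR1 and RHOQ were lower and PTGS2 and SPARC higher in all 3 SIGLEC15 siRNA libraries, while the SIGLEC15 values of the groups overlap.

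The second question was what changed across the transcriptome. Of 18910 genes tested, 879 (4.65%) changed at an edgeR adjusted p under 0.05, 419 higher and 460 lower, and 191 of them by at least 2-fold, 74 higher and 117 lower. The called genes were nearly all protein coding (830), with 13 pseudogenes and 36 other non-coding genes. The median absolute log2 fold change of the called genes was 0.642. In 26.6% of the tested genes (5036) the 3 values of each group did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 3610 genes.

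The lower genes with the smallest p were RHOQ, SCHIP1, PEA15 and KHSRP. RHOQ fell from 57.63 CPM ± 5.9 to 6.84 CPM ± 0.847 (SD, n = 3 each; log2 fold change -3.08, SE 0.134, edgeR adjusted p = 0.000636). PEA15, a cytoplasmic protein that binds ERK, fell from 485.4 to 200.9 CPM, a 2.42-fold change, and KHSRP, an RNA-binding protein of mRNA decay and microRNA maturation, from 263.7 to 112.6 CPM, a 2.34-fold change. RAB5B, an early endosome GTPase, fell 9.25-fold from 58.88 CPM ± 4.95 to 6.37 CPM ± 1.64. TMEM136 fell 5.04-fold from 31.21 to 6.18 CPM. SCHIP1 showed the lowest log2 fold change, -4.36 (SE 0.201), from 28.19 to 1.37 CPM, but it shares exons on the same strand with the read-through gene IQCJ-SCHIP1, which moved the other way, from 26.06 CPM ± 3.86 to 46.61 CPM ± 6.21 (log2 fold change 0.84), and summed over both the log2 ratio was -0.177. The other lower genes in the 10 of largest change were weakly expressed or pseudogenes: KRTAP2-3, H3F3BP1, SERINC2, CEP170P1, ISLR2 and PRR9 had at most 9.58 CPM in the control group and log2 fold changes between -3.59 and -2.19. Values of the pseudogenes H3F3BP1 and CEP170P1 are uncertain where reads fit their parent genes equally well.

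The higher genes with the smallest p were CYP1B1, RNF114, UBFD1 and TDO2. CYP1B1, a cytochrome P450 induced by the aryl hydrocarbon receptor, rose from 103.6 CPM ± 4.84 to 279.6 CPM ± 13.8 (SD, n = 3 each; log2 fold change 1.43, SE 0.0681, edgeR adjusted p = 0.000636). TDO2, the tryptophan dioxygenase that makes kynurenine, rose 9.69-fold from 0.73 to 7.1 CPM. RNF114, a ubiquitin ligase, rose 2.75-fold and UBFD1 4.5-fold. LYPD3, RPL12P42 and RPL21P3 had no counts in the 3 control libraries and were at least 5.22-fold, 11.4-fold and 12.7-fold higher in the SIGLEC15 siRNA group, taken against a floor of 3 counts per library. RPL12P42 and RPL21P3 are ribosomal protein pseudogenes whose reads may be shared with the parent genes. SNORA58B lies in an exon of UBAP2L, and PCDHA13 shares exons with PCDHAC1 and PCDHAC2, so their rises, from 0.0165 to 0.89 CPM and from 0.0215 to 0.777 CPM, are uncertain too. KLRC2, SULT1C2, GGACT and CEACAM1 rose from control levels between 0.0542 and 0.383 CPM to levels between 0.64 and 2.2 CPM. Several of the genes with large folds lost their calls in most alternatives: LYPD3 in 8 of 9, RPL12P42 in 7 of 9, RPL21P3 in 5 of 9, KLRC2, PCDHA13, SULT1C2 and ISLR2 in 7 of 10 and CEP170P1 in 7 of 13. SERINC2, GGACT and CEACAM1 lost theirs in 5 of 10.

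Of 34 gene lists fixed before the data were examined, 33 had at least 5 tested members, and 6 passed camera with its preset inter-gene correlation of 0.01, 3 toward higher and 3 toward lower expression. None of the 6 passed with a correlation estimated per list, so each is given below with that adjusted p as well. That form of camera also uses fewer degrees of freedom, so a lost call need not come from correlation between genes. For TGF-beta target genes the estimate was -0.0175, below the preset value, yet the camera adjusted p rose from 0.000508 to 0.223. A split of the libraries that mixed the groups, and so kept part of their difference, also gave 6 lists at the preset correlation. Counts of members adjusted over the list alone follow those adjusted over all genes.

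Of 27 tested genes of collagens and basement membranes 9 rose, 0 fell and 18 did not pass, with a median log2 fold change of 0.34 (camera adjusted p = 8.32e-06, adjusted p = 0.223 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell, COL13A1, named after its values were seen (log2 fold change -0.36, SE 0.1). LAMA5 and LAMC1, chains of laminin, rose 1.83-fold and 1.71-fold, the latter from 195.9 CPM ± 11.6 to 334.4 CPM ± 23.9 (SD, n = 3 each). COL4A2, a chain of the main basement membrane collagen, rose 1.41-fold from 273.8 to 385.7 CPM, and COL6A1 rose 1.55-fold from 48.1 to 74.66 CPM.

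NF-kB targets and inflammatory cytokines showed the highest median of these lists, a log2 fold change of 0.543 over 23 tested members (camera adjusted p = 4.32e-06, adjusted p = 0.223 with an estimated correlation). Of them 6 rose and 2 fell, and adjusted over the list alone 12 rose and 3 fell. PTGS2, the inducible cyclooxygenase, rose 2.34-fold from 24.1 CPM ± 2.89 to 56.29 CPM ± 5.79 (SD, n = 3 each). TNFAIP3 and NFKBIA, both feedback inhibitors of NF-kB, rose 2.01-fold and 1.68-fold, and the adhesion molecule ICAM1 rose 1.69-fold, a call lost in 5 of 14 alternatives. The 2 members that fell, named here after their values were seen, were the cytokines IL1B, with a log2 fold change of -1.02 (SE 0.179), and LIF, with -0.82 (SE 0.127).

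TGF-beta target genes went both ways. Of 23 tested members 9 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.363 (camera adjusted p = 0.000508, adjusted p = 0.223 with an estimated correlation). COL4A2 and SKI, a corepressor that restrains TGF-beta signalling, were among those that rose, SKI by 1.34-fold, a call lost in 4 of 14 alternatives. CCN2, a matricellular growth factor that is also a YAP target, was among those that fell.

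Of 26 tested YAP target genes 8 fell, 2 rose and 16 did not pass (9 and 2 adjusted over the list alone), with a median log2 fold change of -0.151 (camera adjusted p = 0.00864, adjusted p = 0.519 with an estimated correlation). CCN2 fell 3.06-fold from 337.5 CPM ± 43.2 to 110.3 CPM ± 22.4 (SD, n = 3 each), DLC1 fell 1.71-fold, ANKRD1 1.72-fold and CCN1 1.53-fold. The 2 that rose, named after their values were seen, were LATS2, with a log2 fold change of 0.51 (SE 0.0782), and F3, with 0.53 (SE 0.107). The list passed in 9 of 16 alternatives, with adjusted p between 0.00159 and 0.519. Beside the estimated correlation, its call ended without SIGLEC15 siRNA replicate 1 (camera adjusted p = 0.0685), under limma-trend with either pseudocount (0.0763 and 0.0797) or quantile normalization (0.0633), with a mean FPKM of at least 5 (0.105) and with fry (0.0545).

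Immediate early genes, which answer growth factor and stress signals within minutes, had a median log2 fold change of -0.199 over 22 tested members (camera adjusted p = 0.0144, adjusted p = 0.524 with an estimated correlation). Of them 4 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone. Beside DUSP1, EGR1 fell 2.44-fold from 29.95 CPM ± 2.01 to 12.29 CPM ± 0.31 and JUN 1.77-fold from 223.3 CPM ± 17.9 to 126.4 CPM ± 1.8 (SD, n = 3 each), while BTG2, an antiproliferative gene, rose 2.49-fold. The remaining member that fell was MCL1, by 1.36-fold, a call lost in 6 of 14 alternatives. The list passed in 7 of 16 alternatives, with adjusted p between 0.000365 and 0.524. Beside the estimated correlation, its call ended without control replicate 3, SIGLEC15 siRNA replicate 2 or SIGLEC15 siRNA replicate 3 (camera adjusted p = 0.0631, 0.071 and 0.0536), under limma-trend with either pseudocount (0.0763 and 0.0797) or quantile normalization (0.0633), with fry (0.0545) and with log2 CPM in camera (0.0677), the form that was run first.

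Genes of mitosis and G2/M had a median log2 fold change of -0.168 over 36 tested members (camera adjusted p = 0.00159, adjusted p = 0.524 with an estimated correlation). Of them 4 fell, 0 rose and 32 did not pass (6 and 0 adjusted over the list alone). FOXM1, the transcription factor of the G2/M programme, fell 1.99-fold from 74.76 CPM ± 14.1 to 37.66 CPM ± 7.39 (SD, n = 3 each), CKAP2 fell 1.4-fold, KIF20A 1.3-fold and KIF2C 1.24-fold; FOXM1 and CKAP2 lost their calls in 6 of 14 alternatives, KIF20A and KIF2C in 8 of 14. Genes of DNA replication and G1/S did not pass (36 tested members, median log2 fold change -0.105, camera adjusted p = 0.101), though they passed as lower in 6 of 16 alternatives, among them limma-trend, no filter (0.0304) and without SIGLEC15 siRNA replicate 3 (0.0449).

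**Figure D2:**
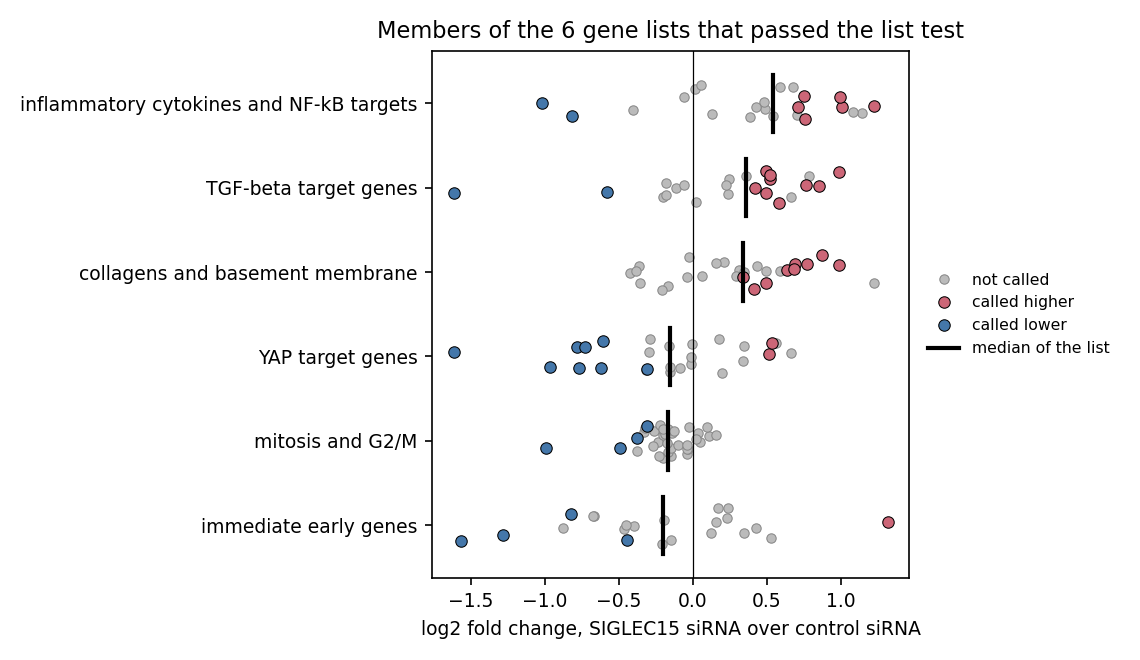
Log2 fold change (SIGLEC15 siRNA over control siRNA) of each tested member of the 6 gene lists that passed camera with its preset correlation; each point is a gene, coloured where its edgeR adjusted p was under 0.05, and the vertical bars are list medians. Medians run from -0.199 for immediate early genes to 0.543 for NF-kB targets and inflammatory cytokines, and members of every list lie on both sides of 0.

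The list of ERK feedback and output genes did not pass as a whole (24 tested members, median log2 fold change -0.0337, camera adjusted p = 0.242; lower in 1 of 16 alternatives, fry, 0.00517), with 4 members lower and 3 higher (6 and 5 adjusted over the list alone). The lower ones were the phosphatases DUSP1, DUSP5 and DUSP6 and the transcription factor EGR1. DUSP6, which acts on ERK, fell 1.62-fold from 276.7 CPM ± 11.2 to 171 CPM ± 4.72 and DUSP5 1.36-fold from 143.1 CPM ± 4.09 to 105.6 CPM ± 4.52 (SD, n = 3 each); DUSP5 lost its call in 5 of 14 alternatives. The higher ones, named after their values were seen, were CCND1, ETV1 and SPRY1, with log2 fold changes of 0.32 (SE 0.0556), 0.51 and 1.15 (SE 0.235). CCND1, which the naming rule takes only from the list of Wnt target genes, lost its call in 7 of 14 alternatives. Members of the MAP kinase cascades did not pass as a list (37 tested, camera adjusted p = 0.171): NRAS and MAP3K5 rose 1.24-fold and 1.5-fold, and the receptor AXL fell 1.24-fold; NRAS and AXL lost their calls in 8 of 14 alternatives and MAP3K5 in 7 of 13.

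The count of changed genes moved by over 1.5 times when any single library was left out: it was 329, 260 and 342 without control replicates 1, 2 and 3, and 392, 266 and 431 without SIGLEC15 siRNA replicates 1, 2 and 3. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.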

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

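The form of camera was settled after the data were seen: log2 CPM was run first, the count object then became the main form, and log2 CPM is an alternative added after seeing the data. The other alternatives were planned. None of the 94 genes that the naming rule takes changed direction under any alternative run; genes named outside it were not followed across alternatives. The count of changed genes (879), higher genes (419) and lower genes (460) stayed within 1.5 times under limma-trend on FPKM with either pseudocount, quantile normalization, no filter, the stricter filter and median-of-ratios scaling, with totals between 633 and 1027. DESeq2 gave 2916 changed genes, 1469 higher and 1447 lower, 401 of them at least 2-fold, and shared 874 of the 879; the cause was not tested. Against 191 genes changed at least 2-fold, limma-trend gave 72 with a pseudocount of 1, 124 with 0.1 and 72 after quantile normalization, where fewer genes were tested (12032) and the pseudocount shrinks folds, and a mean FPKM of at least 5 gave 55 over 6403 genes. Without each library in turn, 260 to 431 genes changed, 108 to 189 higher, 151 to 242 lower and 122 to 167 at least 2-fold, with 1 library fewer in the fit. With the replicate number as a block, 50 genes changed, 15 higher and 35 lower, 40 of them at least 2-fold. Same-numbered libraries did not deviate together (r = -0.0471, 0.011 and -0.058 for numbers 1, 2 and 3). The highest r between different numbers was 0.0685, and not every library correlated best with its own number. No pairing by number was thus seen, but these correlations, taken over all tested genes, cannot exclude it. The block also leaves fewer degrees of freedom for the test. Of the 94 named genes, 77 lost their call under the block, 19 without a filter, and 38 to 45 without each library in turn; 1 lost it under limma-trend.

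The 6 lists became 10 without a filter, 0 with an estimated correlation and 8 with log2 CPM in camera; fry, which does not compare a list with other genes, called 9, without mitosis (adjusted p = 0.0862), YAP targets (0.0545) and immediate early genes (0.0545) and with ERK feedback and output among them (lower, 0.00517); without each library in turn 5 to 9 were called. Collagens, NF-kB targets and TGF-beta targets passed in 15 of 16 alternatives, mitosis in 14, YAP targets in 9 and immediate early genes in 7. SIGLEC15 did not pass in the 9 edgeR alternatives that tested it; settings with an FPKM filter and DESeq2 gave no adjusted p for it. At its level, 6 to 22 counts per library, the interval of the log2 fold change was -2.24 to 0.602. The spread between libraries, beside depth, thus limits what can be said.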

Other observations

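The ATF4 and unfolded protein response list had 6 members higher and 4 lower of 30 tested (edgeR adjusted p under 0.05; camera adjusted p = 0.887): the ER chaperone PDIA4 rose 1.44-fold, while CHAC1, DDIT4 and PPP1R15A, stress genes induced through ATF4, fell 1.77-fold, 1.62-fold and 1.65-fold. Among apoptosis regulators the anti-apoptotic genes BCL2 and MCL1 fell 2.44-fold and 1.36-fold, and BIRC3, an inhibitor of apoptosis, rose 2-fold (camera adjusted p = 0.679); BCL2 lost its call in 6 of 10 alternatives and BIRC3 in 8 of 13. The glucose transporter SLC2A3 rose 2.38-fold from 34.66 CPM ± 1.67 to 82.32 CPM ± 4.91 (SD, n = 3 each), and of 30 glycolysis and hypoxia genes PFKP, PGAM1 and ADM also rose, by 1.24-fold to 1.51-fold, with 0 lower (camera adjusted p = 0.0995; higher in 1 of 16 alternatives, fry, 0.0308); PFKP lost its call in 8 of 14 alternatives and PGAM1 and ADM in 7 of 14. The chaperone HSP90AB1 fell 2.1-fold from 2795 CPM ± 137 to 1328 CPM ± 56.7, and the matrix protein SPARC rose 1.75-fold from 345.9 CPM ± 6.34 to 604 CPM ± 7.68.

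In the RNA interference machinery, 2 of 13 members passed: DROSHA, which makes the first cut of microRNA precursors, fell 1.45-fold, and DICER1, which makes the next, rose 1.71-fold; DICER1 lost its call in 6 of 14 alternatives and DROSHA in 2 of 14. The antigen presentation list leaned higher, with 15 of 20 log2 fold changes above 0 and a median of 0.209, but did not pass (camera adjusted p = 0.101), and the 1 member called, CALR, fell; the list passed as higher in 4 of 16 alternatives, without control replicate 3 (0.0405), without SIGLEC15 siRNA replicate 3 (0.0434), without a filter (0.0442) and with log2 CPM in camera (0.0456). Of 30 interferon-stimulated genes 1, IRF1, rose (camera adjusted p = 0.0854); this list passed as higher in 4 of 16 alternatives, without control replicate 3 (0.0405), without a filter (0.0156), with fry (0.0315) and with log2 CPM (0.0476). In edgeR 0 of 74 cytosolic ribosomal protein genes passed (4 at an unadjusted p under 0.05, 3 in DESeq2), 0 of 13 mitochondrial mRNAs (3 and 3), 0 of 26 genes of the Siglec family and sialic acid metabolism (4 and 3) and 0 of 8 osteoclast and Siglec-15 adaptor genes (0 and 0). Of the leukocyte and macrophage markers 4 were expressed enough to test, and 0 passed (1 and 1).

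The scan of 7-base sequences in 3' UTRs was prompted by the called genes, and its prediction was written before it was run; the tests of endogenous microRNA sites, of SIGLEC15 loss and of overlapping genes, the counts of sites among called genes, the size of the GC and length trend and the comparisons of library pairs were chosen only after the results they address had been seen. AGGCTCA (1671 genes, t = -12.25) and CAGGCTC (1975 genes, t = -12.24) went most with lower expression, past the 5th percentile of shuffled genes (-4.65; permutation p = 0.001, the smallest that 1000 shuffles can give). Together they make up CAGGCTCA: the median log2 fold change was 0.019 (SD 0.461) in 9359 genes without its core AGGCTC, -0.0158 (SD 0.476) with the core only, and -0.0823 (SD 0.46) in 636 genes with all 8 bases. In all 9 pairs of a SIGLEC15 siRNA library with a control library the t of AGGCTCA lay between -9.44 and -5.84, against -1.67 to 0.82 in the 6 pairs within groups. The sequence was picked on these genes and libraries, so the medians and pairs describe it and are no further test. On the side of higher expression the leading sequences were GCACTTT (t = 7.34), TGGTGCT (t = 6.63), TGTTTAC (t = 6.43) and ACTGTGA (t = 5.93), past the 95th percentile of shuffled genes (4.68). These are the sites of the microRNA families miR-17, miR-29, miR-30 and miR-27. On this side 11 sequences passed the shuffled bound at a permutation p under 0.05. Of these, only the 4 equal a full 7-base site of the 61 families, the only form of site that was matched. Others share most of a site: CACTTTA (t = 5.56) shares CACTTT with GCACTTT. GCTGCTA (t = 4.85) shares GCTGCT with TGCTGCT, the site of miR-15/16. The 4 are thus not a full count of microRNA sites.

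A hypothesis for the lower genes is that the SIGLEC15 siRNA acted on other mRNAs through its seed, the bases near the 5' end of a guide strand that pair like those of a microRNA, since a lowest t of -12.25 could have stayed above the shuffled bound and did not. AGGCTCA lies in 2 of the 3 annotated protein-coding SIGLEC15 transcripts, where 10% of the scanned sequences lie in at least 1, so a siRNA against SIGLEC15 may carry the matching seed. Of the 423 called lower genes with a 3' UTR, 185 had no core AGGCTC there. The core was in 56.3% of these genes, in 30.5% of 12780 tested genes not called and in 26.7% of the called higher genes. Much of the core's presence among the lower genes is thus shared with genes that were not called. AGGCTCA or CAGGCTC was in 42.8% of the called lower genes and in 40.6% of those lower at least 2-fold. The shares were 19.9% of genes not called and 15.1% of the called higher genes. The sequence was picked on these genes, so the shares are no further test. A bias of GC content or transcript length as the whole cause is argued against by the small size of its trend, which over 13782 genes reached from -0.0463 to 0.0405 on the log2 scale, while the called lower genes had a median of -0.678 (-0.679 without the trend); loss of SIGLEC15 as the driver stays open, since the upper end of the 95% interval of its log2 fold change was 0.602. For DUSP1, the 672-base 3' UTR held 0 sites of AGGCTCA, which had been set as the bound against direct silencing. By that prediction as written, direct silencing was not met. The UTR did hold AGGCTCT (t = -10.04) and GAGGCTC (t = -5.95), both among the called sequences, which the bound had not covered. They overlap at its 1 site of the core. Of genes with the core only, the class of DUSP1, 3.89% were called lower, against 1.98% of genes without the core. That class pools all other bases beside the core, so its share is not that of genes with AGGCTCT. Direct silencing of DUSP1 therefore cannot be told apart from a change downstream.

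For the higher genes, silencing by the seed of the control siRNA in the control libraries cannot be told apart from a change of microRNA action, because the sequence with the highest t, 7.34, is itself a microRNA site. A candidate explanation is that endogenous microRNAs acted less in the SIGLEC15 siRNA libraries, for example if that siRNA took up more of the shared Argonaute proteins. Over the sites of 61 conserved microRNA families the median t was 1.63, above the highest of 10000 random sets of sequences matched on GC and gene number (0.59). Without the 4 sites past the shuffled bound it was 1.14, against a 95th percentile of 0.14. Several sites share bases, however: GCAC lies in GCACTTT, TTGCACT (t = 4.17) and TTTGCAC (t = 4.02). Their t values are therefore not independent. The random sets were matched on GC and gene number, not on such overlap, so their spread may be too narrow. The families were also written down after the scan had been seen. The comparison thus describes these sites and cannot decide whether microRNA action changed. GC content and transcript length as the whole cause are argued against by the same trend, at most 0.0405, beside a median log2 fold change of 0.592 in the called higher genes (0.587 without the trend).

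Of the 191 genes changed at least 2-fold, 14 share exon sequence with another tested gene on the same strand, and in 9 of them (64.3%, exact 95% interval 35.1 to 87.2) the summed counts changed by less than 0.5 times as much on the log2 scale. A shift of reads between overlapping genes in the counting cannot be told apart from a change of the gene itself, because an abundant partner such as UBAP2L for SNORA58B sets the sum whatever the smaller gene does. Only SCHIP1 had a partner called in the opposite direction, IQCJ-SCHIP1, and for that locus a switch between transcripts or a different assignment of reads may apply.

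The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 879 changed genes, 419 higher and 460 lower, and the highest other split 11, 5 higher and 6 lower; 1 of the 10 splits, the real one, gave as many in each of these counts. For genes changed at least 2-fold the values were 191 and 10. For lists called by camera with its preset correlation, 2 of the 10 splits gave 6. The split that equalled the real one had 11 changed genes, and the remaining splits gave 0 to 3 lists. A split with 0 changed genes gave 3 lists. The preset test thus also called lists where the groups were mixed, and the number of lists does not set the real split apart. Every other split put 2 libraries of a group with 1 of the other, so it kept part of the group difference. The rest of that difference widened the spread within each side, which lowers the count of changed genes. These splits therefore cannot show how many genes or lists are called where no group difference exists.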
